A study of Mus musculus with 6 samples.

How the data were processed

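Gene expression was measured in total RNA from hearts of FVB mice on 6 Illumina bead arrays. The labels give 4 groups: 1 wild-type sham array, 2 wild-type TAC arrays, 1 array of sham-operated JMJD2A-transgenic mice and 2 transgenic TAC arrays. TAC is thoracic aortic constriction, a band that loads the left ventricle with pressure. The age is 8 weeks in the labels, whereas the design text of the series gives it in years; the hearts were taken 3 weeks after surgery. Per the labels' protocols, RNA was extracted with Trizol, treated with DNase I, checked on a Bioanalyzer and copied into biotinylated cRNA with a TotalPrep kit. The labels do not say whether each array holds RNA of a separate animal or of a pool, so p-values measure the spread between these samples, part of which may be technical.

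The deposited table holds 1 intensity per probe and array on a linear scale, between 30.83 and 25873 on every array. The array medians lay between 56.3 and 56.4, and the sorted columns differed from their mean by at most 0.0064 on the log2 scale, the pattern left by quantile normalization. The authors' software, background correction and normalization are not given in the sources used here. The deposited normalization was kept, 12 values below 32 were set to 32, and log2 was taken. Background was not subtracted in this work, so a fold against a group near or below the array median understates the change.

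Of 45281 probes, 34885 had 1 gene symbol in the platform annotation used here, 18 had several and 10378 had none. Symbols were updated by gene identifier through a gene table of assembly GRCm38.p6, which was used for names and gene order only. Each of 19053 genes was represented by its brightest probe; 9171 genes had more than 1 probe. Genes whose probe lay above the 50th percentile of all 34885 probes with 1 gene symbol, an intensity of 58.7, were tested. This left 11166 genes.

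Tests used lmFit and eBayes with an intensity trend in limma 3.58.1 (R 4.3.3), with Benjamini-Hochberg adjustment over the 11166 genes and a threshold of 0.05; errors are standard errors (SE) of these fits unless an SD is named. A fit of the 4 groups gave TAC against sham within each genotype, transgenic against wild type after TAC, and the difference of the TAC responses, with 2 residual and 6.25 prior degrees of freedom. Each sham group holds 1 array, which was assumed to vary like the TAC arrays. A model of surgery plus genotype gave TAC against sham over both genotypes and transgenic against wild type over both surgeries, with 3 residual and 6.14 prior degrees of freedom. The sham arrays were compared with each other by size only, counting log2 differences of at least 1.

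A total of 28 gene lists were fixed, of pathways and of cell type markers. Some lists share genes, so their results are not independent. Among others, the matrix and fibroblast lists share Col1a1, Col1a2, Col3a1, Dcn, Lum, Mfap4 and Pcolce. The fetal list shares Nppa, Myl4 and Myl7 with the atrial list, and Acta1, Acta2 and Fhl1 with the SRF list. They were tested with camera in limma at its preset inter-gene correlation of 0.01, with adjustment over the lists of a comparison, and again with an estimated correlation and with fry. Fry's p asks whether the genes of a set move, on balance, one way, and neither that nor its mixed p compares the set with other genes. Mesothelial markers and sex-linked genes had fewer than 5 tested members and were not tested as lists. For the sham pair, a list's median was placed among 10000 random lists of its size matched on intensity.

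Genes were named by a fixed rule: for each comparison the 12 largest increases and 12 largest decreases among genes past the test whose arrays do not overlap, filled to 5 per direction by smallest p. Predicted genes, known by their symbols, were passed over: 1 increase and 2 decreases among the 106 genes past the test between genotypes over both surgeries, and none past the other tests. For the sham pair the rule took the 8 largest differences each way. Kdm4a, Fhl1, Nppa, Nppb, Myh6, Myh7, Acta1, Ankrd1, Ccn2, Postn, Timp1 and Atp2a2 were always considered, as were the 4 members of a list with the smallest p. The 3 Postn probes lay below the intensity filter. The groups, the tests, the lists, the naming rule and most of the other settings below were chosen before the data were examined.

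The steps were tested on simulated data in which 200 of the 11166 genes were changed. For transgenic against wild type over both surgeries, 83.6% of genes changed by log2 1 were called; for TAC against sham over both genotypes this was 73.1%, after TAC between genotypes 59.7%, within wild type 19.4%, within transgenic arrays 20.9% and for the difference of the TAC responses 1.5%. Between 0 and 9 of 10966 unchanged genes were called. A simulated list of 20 independent genes raised by log2 0.5 passed camera at the preset correlation in every comparison, and 2 of 26 unchanged lists passed there for TAC against sham over both genotypes. With an estimated correlation its adjusted p was 0.0366 for the genotypes over both surgeries and 0.0978 to 0.985 in the others. In the latter that setting missed a raised list of independent genes. For TAC against sham over both genotypes, the estimated correlations of the real lists ran from -0.059 to 0.70. They were 0.62 for matrix and 0.35 for fetal genes. With independent genes, the simulation cannot tell whether the preset suits such lists or whether the estimated setting misses them.

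Results were recomputed with other filters, floors, probe rules and thresholds, median centring, quantile normalization again, fits without a trend or with robust variances, the TAC number as a replicate block, fits of the TAC arrays only, other list tests and leaving out each array. An Xist level covariate and leaving out the 2 arrays of low Xist were chosen after seeing the data. The latter leaves 1 wild-type sham, 1 wild-type TAC and 2 transgenic TAC arrays, with 1 residual degree of freedom. In that fit TAC against sham is 1 wild-type array against 1. A call lost there does not show dependence on the arrays left out. Plots were drawn with matplotlib in Python.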

Results

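Heart gene expression was measured on 6 arrays: 1 of wild-type sham, 2 of wild-type TAC, 1 of transgenic sham and 2 of transgenic TAC mice. The transgene drives JMJD2A, a histone lysine demethylase encoded by Kdm4a, in the heart. Over all probes, array pairs correlated at r = 0.984 to 0.994 on the log2 scale. The SD of the log2 difference was 0.200 between the wild-type TAC arrays and 0.306 between the transgenic TAC arrays, the largest of all pairs, those between groups included. In a principal component analysis the first component (36.4% of variance) followed neither factor, whereas the second (30.6%) placed the 3 wild-type arrays at 0.23 to 20.9 and the 3 transgenic arrays at -16.6 to -1.88. Xist, transcribed from the silenced X chromosome of female cells, was low in wild-type TAC 2 (log2 5.38) and transgenic sham (5.41) and lay between 10.36 and 11.03 on the other 4 arrays. The labels give no sex.

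Kdm4a had 3 probes. The tested probe lay between 6.45 and 6.75 on all 6 arrays, and its log2 difference between transgenic and wild-type arrays was 0.01 ± 0.12 (3 against 3 arrays, adjusted p = 0.994). A second probe was at 6.40 to 6.49 in wild-type arrays, 7.03 in transgenic sham, 6.86 in transgenic TAC 1 and 6.32 in transgenic TAC 2. The remaining probe lay below the intensity filter. Where the probes lie relative to the transgene, and which species' sequence it carries, is not given in the sources used here, so these values do not check the genotype labels. The arrays labelled transgenic are called transgenic throughout.

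TAC against sham over both genotypes asks which genes pressure overload changed. Acta1, the skeletal alpha-actin of fetal and overloaded heart muscle, rose 2.13-fold (log2 1.09 ± 0.08, 4 TAC against 2 sham arrays, adjusted p = 0.00403). It stood at 13.28 and 12.85 in the wild-type and transgenic sham arrays and at 13.95 to 14.38 in all 4 TAC arrays. The natriuretic peptide genes Nppb (0.72 ± 0.09, adjusted p = 0.101) and Nppa (0.82 ± 0.13, adjusted p = 0.225) and the uridine kinase gene Uck2 (1.05 ± 0.15, adjusted p = 0.203) were above both sham arrays in 4 of 4 TAC arrays without passing. So were the matrix genes Mfap5 (1.59 ± 0.28) and Timp1 (1.64 ± 0.33) and the growth factor gene Ccn2 (1.09 ± 0.25), with adjusted p between 0.225 and 0.274. Without 1 array Nppb ranged from 0.68 to 0.76, Nppa from 0.52 to 1.13 and Timp1 from 1.22 to 2.05. Myh7, the slow myosin heavy chain, had the larger difference of 1.85 with an SE of 0.62 and overlapping arrays (adjusted p = 0.420), and Myh6 stood at 0.13 ± 0.11 by its tested probe and at -0.22 by the median over its probes. In transgenic arrays the tested Myh6 probe gave 0.31 and a second one -1.24. Among lower genes, Lypd2 (-0.73), Tbc1d10c (-1.28), Epop (-0.93), the hepcidin gene Hamp2 (-0.76) and Ttll1 (-1.02) all had an adjusted p of 0.225. Tbc1d10c ranged from -1.68 to -0.89 without 1 array, and no decrease was left by the median over its probes. Acta1 was the only gene of 11166 that passed in limma, while 1033 genes had an unadjusted p under 0.05 against 558 by chance; 16.5% of genes did not overlap between TAC and sham arrays, where chance gives 13.3%. Its adjusted p was 0.238 without the wild-type sham array, 0.118 without the transgenic sham array, 0.0798 without wild-type TAC 1 and 0.0869 without wild-type TAC 2. It was 0.121 without the intensity trend and 0.0758 with Xist as a covariate, and 37 genes passed without transgenic TAC 1. Without both arrays of low Xist, which leaves 1 wild-type TAC array against 1 sham array, Acta1 stood at 1.10 ± 0.21. Its difference stayed between 1.08 and 1.11 in all of these. Nppa averaged an intensity of 22029 and Acta1 of 21018 in wild-type TAC arrays, and Nppb averaged 23733 in transgenic ones, beside a highest intensity of 25873 on each array, and a dimmer Ankrd1 probe gave 1.71 in wild type where the tested one gave 0.41.

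**Figure D1:**
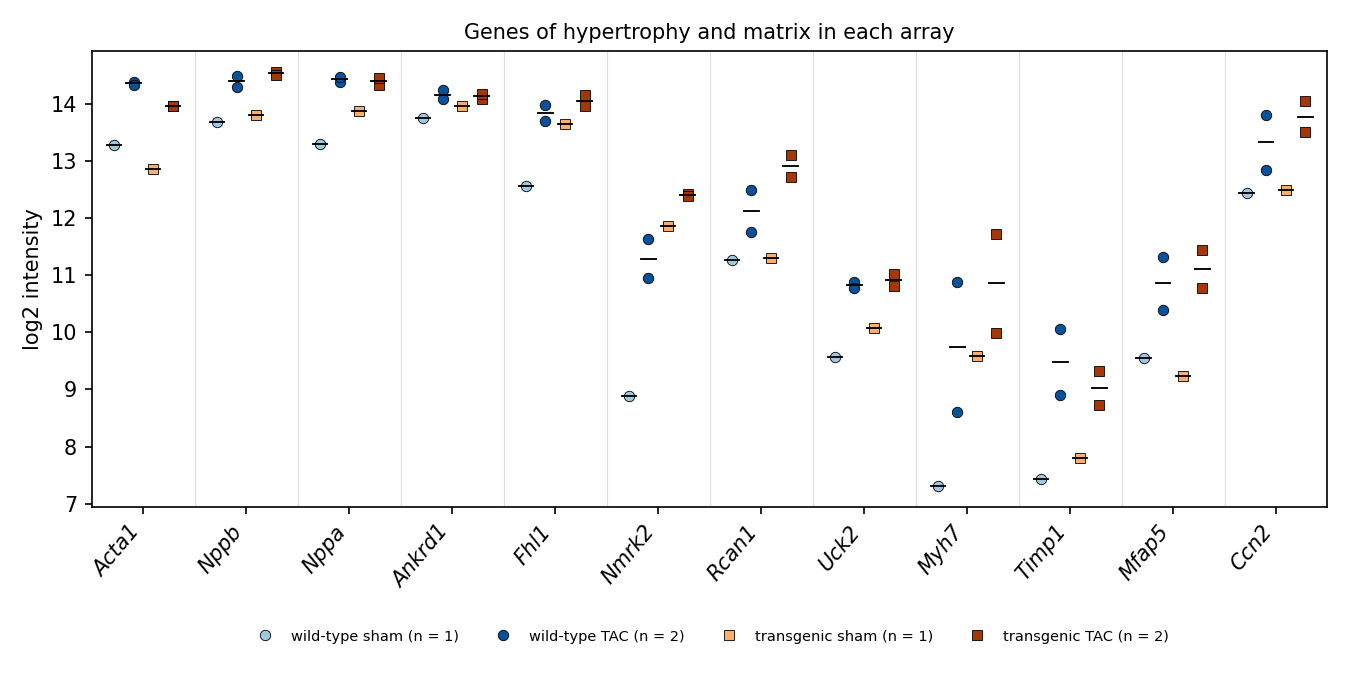
Log2 intensity of 12 genes of hypertrophy and matrix on each of the 6 arrays, with a point per array, a line at the group mean and 1 or 2 arrays per group. Acta1 stands above 13.9 in all 4 TAC arrays and below 13.3 in both sham arrays.

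As a group, matrix genes lay higher after TAC over both genotypes: 45 of 51 members were higher, with a median log2 difference of 0.81. Of these 31 passed when adjusted over the list alone and 0 over all genes, led by Mfap5, Lum, Timp1 and Col8a1 (1.51 ± 0.32). The fetal and hypertrophic genes followed, with 16 of 17 higher, a median of 0.84, 12 adjusted over the list alone and 1 over all genes. Fibroblast markers were higher in 13 of 15, with Serpinf1 at 1.06 ± 0.19 and Col1a1 at 1.51 ± 0.36, and 6 passed adjusted over the list alone against 0 over all genes. Genes of fuel oxidation lay lower: 30 of 32 fatty acid oxidation genes (median -0.35, with Acot1 at -0.79 and Mlycd at -0.63), 17 of 18 tricarboxylic acid cycle genes (-0.31, with Idh2 at -0.48) and 60 of 69 oxidative phosphorylation genes (-0.11). Of calcium handling and channel genes 21 of 26 were lower (-0.13), and 4, Kcnv2, Kcnd2, Kcnh2 and Ryr2, passed adjusted over the list alone. Immediate early genes were higher in 11 of 14, with Egr2 at 0.90 ± 0.21 and Egr3 at 1.03 ± 0.28. Camera gave adjusted p = 6.61e-27 for matrix, 7.03e-18 for fetal, 4.97e-10 for fatty acid oxidation, 1.03e-07 for tricarboxylic acid cycle, 1.52e-07 for fibroblast, 4.61e-07 for oxidative phosphorylation, 6.93e-04 for calcium and 7.52e-04 for immediate early genes. With an estimated correlation all of these had adjusted p = 0.426 except immediate early genes at 0.464, and none of the 26 tested lists passed that setting or fry in any comparison. A further 6 lists passed at the preset correlation but not without 1 array. These were SRF and MRTF targets (0.365 without wild-type sham), atrial markers (0.247 without wild-type sham), macrophage markers (0.0818 without wild-type sham) and endothelial markers (0.150 without transgenic TAC 2). The others were interferon response genes (0.149 without wild-type sham, 0.0968 without wild-type TAC 2) and cell cycle genes (0.271 without transgenic sham, 0.549 without transgenic TAC 2). Calcium genes had adjusted p = 0.136 without both arrays of low Xist.

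Within wild type, Nmrk2, a nicotinamide riboside kinase, had the smallest p, with a difference of 2.40 ± 0.28 (5.27-fold, 2 TAC arrays against 1 sham). Nppa (1.13 ± 0.14), Acta1 (1.08 ± 0.14) and the LIM protein gene Fhl1 (2.42-fold) stood beside it, all at adjusted p = 0.127 and higher in 2 of 2 TAC arrays. The transferrin receptor gene Tfrc was at 1.52 ± 0.24, Timp1 at 2.05 ± 0.46 and Myh7 at 2.44 ± 0.89, while Tbc1d10c (-1.68), Lypd2 (-0.87), Ano10 (-1.11), Timp4 (-0.95) and Npy4r (-0.78) were lower. No gene passed in limma (0 of 11166), and 398 had an unadjusted p under 0.05 against 558 by chance. Over all genes 73.1% did not overlap between TAC and sham arrays, where chance gives 66.7%. With Xist as a covariate 10 genes passed. Of the fetal and hypertrophic genes 16 of 17 were higher (median 1.08), 13 of them past the test adjusted over the list alone and 0 over all genes. Camera gave adjusted p = 1.60e-27 for this list, 5.66e-22 for matrix genes (48 of 51 higher), 2.92e-09 for SRF and MRTF targets (20 of 23 higher, median 0.40) and 6.08e-08 for atrial markers (8 of 9 higher). Fatty acid oxidation (-0.28), fibroblast marker (0.23) and oxidative phosphorylation (-0.08) lists also passed and held without each array. These 7 lists had adjusted p = 0.638 with an estimated correlation. Another 7 lists lost the call without wild-type TAC 1 or wild-type TAC 2: macrophage (0.193 without the latter), interferon (0.308, latter), adipocyte (0.174, latter), immediate early (0.867, former), tricarboxylic acid cycle (0.111, former), endothelial (0.174 and 0.0817) and calcium genes (0.0570 and 0.123).

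Within transgenic arrays, Xist was low in sham (5.41) and high in TAC 1 and TAC 2 (10.36 and 11.03). An effect of TAC therefore cannot be told apart from a possible difference in sex for any gene or list in this comparison. Acta1 stood at 1.11 ± 0.14 (2.15-fold, 2 TAC arrays against 1 sham, adjusted p = 0.214). Fgf6 (1.95 ± 0.30), Rasl11b (1.32 ± 0.23), the calcineurin regulator Rcan1 (1.61 ± 0.30) and Nppb (0.73 ± 0.14) were higher in 2 of 2 TAC arrays, and the kallikrein gene Egfbp2 (-1.11), the water channel gene Aqp4 (-1.28), Hamp2 (2.01-fold), the inducible heat shock gene Hspa1a (-1.43) and Inmt (-1.71) were lower. No gene passed in limma (0 of 11166), and 543 had an unadjusted p under 0.05 against 558 by chance. Over all genes 61.1% did not overlap between TAC and sham arrays, where chance gives 66.7%. Leaving out a transgenic TAC array leaves 1 array against 1 and the spread of the wild-type TAC pair alone, so no count is given for it. All 18 tricarboxylic acid cycle genes were lower (median -0.51, with Cs at -0.64 ± 0.17 and Dld at -1.11 ± 0.30, camera adjusted p = 4.78e-10), and 12 of 14 heat shock genes were lower (-0.14, adjusted p = 0.00185). Matrix genes were higher in 47 of 51 (0.79, adjusted p = 3.26e-21) and fetal and hypertrophic genes in 16 of 17 (0.52, adjusted p = 5.26e-10), with 5 of the latter adjusted over the list alone and 0 over all genes. Fibroblast markers were higher in 13 of 15 (0.63), fatty acid oxidation genes lower in 26 of 32 (-0.42), oxidative phosphorylation genes in 57 of 69 (-0.14) and calcium genes in 23 of 26 (-0.17). All 8 of these had adjusted p = 0.516 with an estimated correlation. With Xist as a covariate matrix genes had adjusted p = 0.492, fetal genes 0.705 and fibroblast markers 0.421. Lymphocyte markers, immediate early genes, cell cycle genes and endothelial markers passed too, but lost the call with 1 transgenic TAC array left out. In that fit of 1 array against 1, cell cycle genes and endothelial markers had a turned direction.

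**Figure D2:**
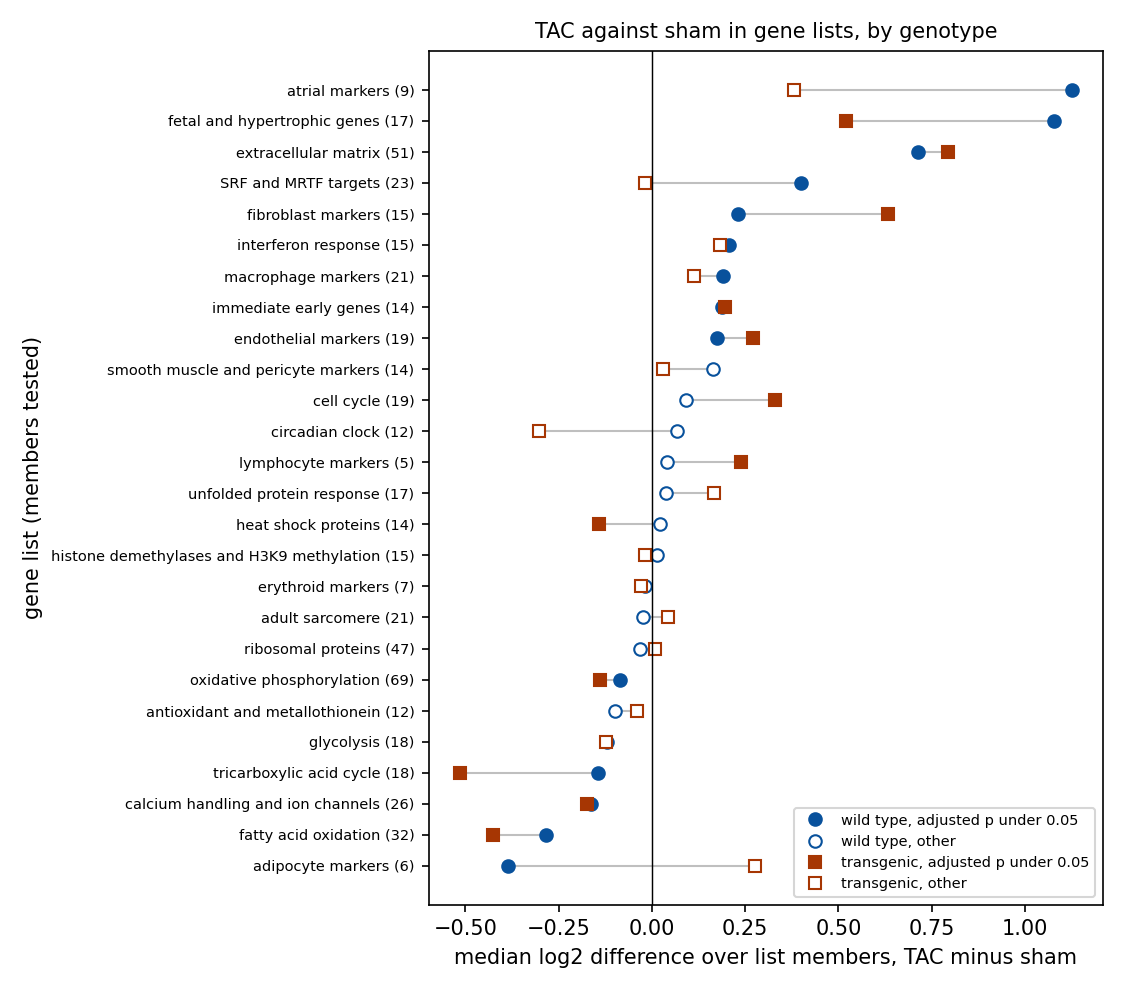
Median log2 difference of TAC minus sham over the members of each of 26 gene lists, in wild-type (circles) and transgenic arrays (squares), filled where camera at the preset correlation gave an adjusted p under 0.05. Fetal and hypertrophic genes stand at 1.08 in wild type and 0.52 in transgenic arrays.

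The difference of the TAC responses asks whether the transgene altered what TAC changed. Nmrk2 had a smaller TAC difference in transgenic arrays (-1.86 ± 0.39), and its transgenic sham value of 11.87 lay above both wild-type TAC values. Hspa1a (-1.60 ± 0.36), the complement gene C4a (-1.84 ± 0.42), Serpina3n (-1.33 ± 0.30) and Egfbp2 (-1.21 ± 0.20) also had negative differences. Npy4r (1.24 ± 0.25), Cyp2e1 (1.58 ± 0.44), Adipoq (1.88 ± 0.53), Nkg7 (0.80 ± 0.23) and Xist (7.85 ± 2.23) had positive ones, and Acta1 stood at 0.03 ± 0.19. The value of Xist comes from wild-type TAC 2 (5.38) and transgenic sham (5.41), which both enter this difference with a minus sign. Sex of the animals therefore cannot be told apart from a differing TAC response for any gene or list here. No gene passed in limma (0 of 11166, smallest adjusted p 1.00), and 183 had an unadjusted p under 0.05 against 558 by chance. With Xist as a covariate 5 passed. The transgenic minus the wild-type TAC difference was negative for 12 of 17 fetal and hypertrophic genes (median -0.43, camera adjusted p = 5.48e-06), 18 of 23 SRF and MRTF targets (-0.22), 8 of 9 atrial markers (-0.54) and 10 of 14 heat shock genes (-0.29). The median TAC difference of heat shock genes was 0.02 in wild type and -0.14 in transgenic arrays, and that of SRF and MRTF targets was 0.40 and -0.02. With an estimated correlation each had adjusted p = 0.795, and heat shock genes had 0.0761 by the median over a gene's probes. Tricarboxylic acid cycle genes (16 of 18 negative, 0.151 without transgenic TAC 2), adipocyte markers (4 of 6 positive, 0.0628 without transgenic TAC 1) and lymphocyte markers (4 of 5 positive, 0.0594, 0.0628 and 0.0517 without wild-type TAC 1, transgenic TAC 1 and transgenic TAC 2) lost the call. Across genes, which are not independent replicates, the TAC differences of the genotypes correlated at r = 0.432 (Spearman's rho 0.386) and 62.2% of genes had the same sign. With 1 TAC array per genotype r was 0.0714 for wild-type TAC 2 with transgenic TAC 1 and 0.290 to 0.458 for the other 3 pairs.

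Transgenic against wild type over both surgeries asks what differed with the transgene regardless of surgery. The synaptic adhesion gene Nrxn3 rose 17.3-fold (log2 4.11 ± 0.16, 3 against 3 arrays, adjusted p = 9.10e-06), from 5.51 to 5.76 in wild-type arrays, below the array median, to 9.49 to 10.15. The sulfotransferase gene Sult4a1 rose 8.94-fold (3.16 ± 0.16, adjusted p = 5.04e-05), from wild-type intensities of 46.9 to 47.0 by group, beside an array median of 56.3 and a lower quartile of 46.5. The muscle transcription cofactor gene Vgll2 (2.41 ± 0.19), Rnf208 (2.34 ± 0.16), the sodium-proton exchanger gene Slc9a3 (2.29 ± 0.13), transthyretin Ttr (2.06 ± 0.18), the homeobox gene Alx4 (2.02 ± 0.21) and the creatine kinase gene Ckmt1 (2.02 ± 0.16) rose with adjusted p of at most 0.00267. Rps4l (2.04 ± 0.26), Mthfd2, an enzyme of mitochondrial folate metabolism (1.86 ± 0.21), Cideb (1.60 ± 0.15) and Ric3 (1.56 ± 0.16) rose too. The homeodomain gene Hopx fell by 1.72 ± 0.15 (adjusted p = 0.00134), smooth muscle actin Acta2 fell by 1.67 ± 0.23 (adjusted p = 0.0118) and the carboxylesterase gene Ces1d fell by 1.82 ± 0.25 (adjusted p = 0.0118). Abcb4 (-1.46), Slc24a2 (-1.36), Pdlim3 (-1.31), Slc38a3 (-1.25), Ano10 (-1.25), Ttll1 (-1.17), Lamb3 (-1.16), the potassium channel gene Kcnd2 (-1.13) and Rgs6 (-1.12) fell as well. Of the always considered genes, Acta1 was lower at -0.41 ± 0.08 without passing (adjusted p = 0.0555). In all 106 genes passed, 74 higher and 32 lower in transgenic arrays, each with no overlap between the 3 and 3 arrays, and 1289 genes had an unadjusted p under 0.05 against 558 by chance. Over all tested genes 1803, or 16.15%, did not overlap, where chance gives 10%.

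**Figure D3:**
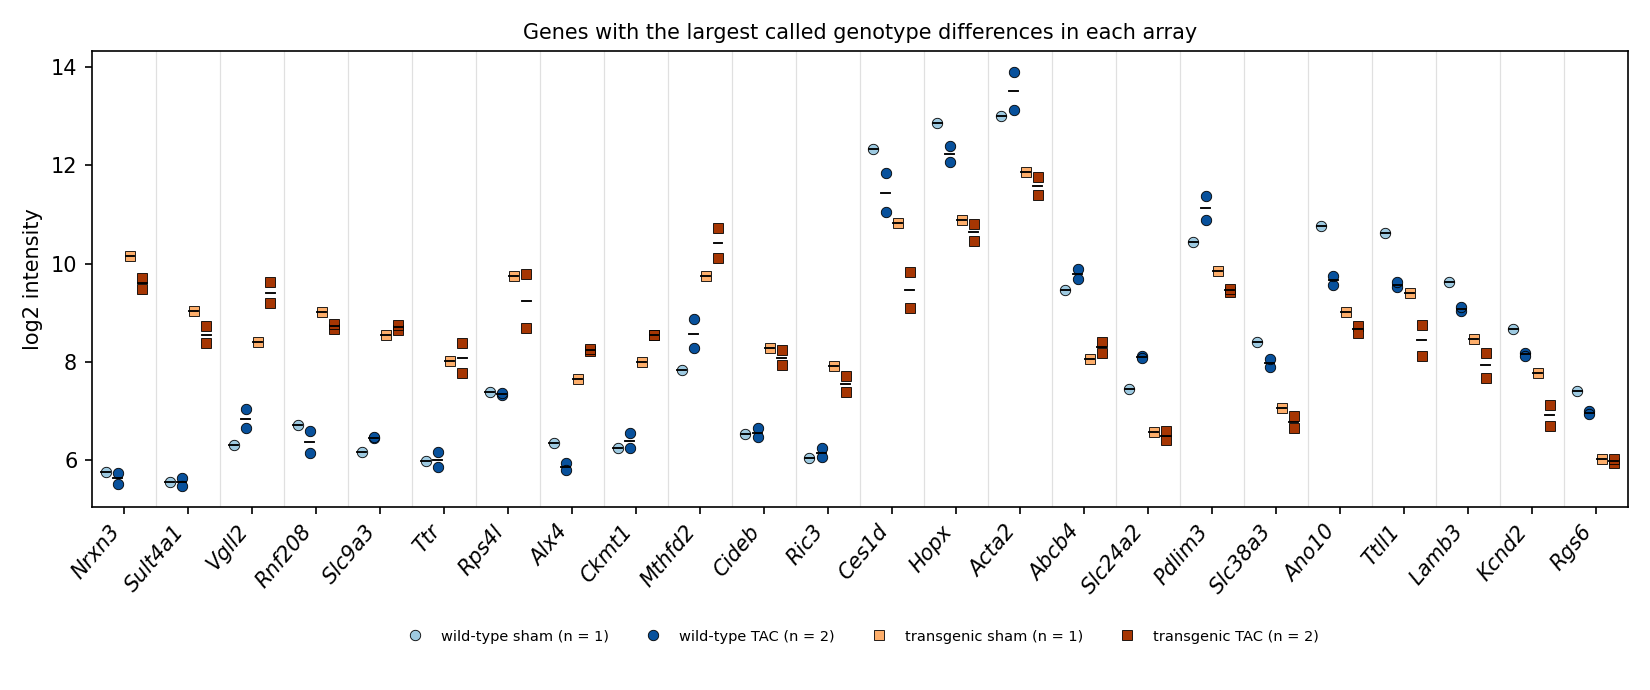
Log2 intensity on each of the 6 arrays of the 12 largest increases and 12 largest decreases that passed between transgenic and wild-type arrays, predicted genes left out, with a point per array and a line at the group mean. Nrxn3 and Sult4a1 stand below 6 in every wild-type array and above 8 in every transgenic array.

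The number of genes past the test between genotypes depended on single arrays. It was 24 without wild-type sham, 24 without transgenic sham, 30 without wild-type TAC 1, 32 without wild-type TAC 2, 132 without transgenic TAC 1 and 474 without transgenic TAC 2. Of the 24 genes named above, 13 passed with each array left out: Nrxn3, Sult4a1, Vgll2, Rnf208, Slc9a3, Ttr, Alx4, Ckmt1, Cideb, Ric3, Hopx, Acta2 and Abcb4. By the median over a gene's probes, Acta2 had adjusted p = 0.201 and Hopx 0.0768. Without both arrays of low Xist, Nrxn3 stood at 3.86 ± 0.34 on the 4 arrays left. That fit sets 2 transgenic TAC arrays against wild-type TAC 1 alone, with 1 residual degree of freedom. It cannot show whether the calls depend on the arrays left out. Rps4l, Ano10, Ttll1, Lamb3 and Kcnd2 lost the call without any 1 of wild-type sham, transgenic sham, wild-type TAC 1 and wild-type TAC 2, with adjusted p from 0.0547 for Ano10 to 0.219 for Ttll1. Slc24a2 had 0.0657 without wild-type TAC 1 and 0.0699 without wild-type TAC 2, and Pdlim3 had 0.146 and 0.196 there and 0.0504 without transgenic TAC 1. Ces1d had 0.0726, 0.0533 and 0.0675, and Slc38a3 0.0844, 0.0514 and 0.0947, without wild-type sham, wild-type TAC 2 and transgenic sham. Mthfd2 had 0.0574 without wild-type sham and 0.0633 without transgenic sham, and Rgs6 had 0.0636 without transgenic sham. With Xist as a covariate Kcnd2 (0.0567), Lamb3 (0.0563), Ttll1 (0.0707) and Pdlim3 (0.0900) lost the call, and with a floor of 64 Kcnd2 and Ttll1 (0.0513 each) and Pdlim3 (0.0921) did.

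Heat shock genes lay higher in transgenic arrays over both surgeries, in 13 of 14 members with a median of 0.21, led by Hsp90aa1 (0.66 ± 0.15) and Hspa1a (1.09 ± 0.29); 2 passed adjusted over the list alone and 0 over all genes. Macrophage markers were higher in 19 of 21 (median 0.23), and of these the class II invariant chain gene Cd74 rose by 1.00 ± 0.19 (adjusted p = 0.0495). Smooth muscle and pericyte markers were lower in 13 of 14 (-0.31), with the smooth muscle coactivator gene Myocd at -0.73 ± 0.16, and 17 of 19 endothelial markers were lower (-0.25). Of immediate early genes 9 of 14 were higher, with Egr1 past the test at 0.97 ± 0.17 (adjusted p = 0.0408), and 17 of 23 SRF and MRTF targets were lower (-0.17). Camera gave adjusted p = 2.87e-04 for heat shock, 6.30e-04 for macrophage, 0.00141 for smooth muscle, 0.00500 for endothelial, 0.00644 for immediate early genes and 0.0301 for SRF and MRTF targets. For endothelial markers adjusted p = 0.856 with an estimated correlation, and for the other 5 lists 0.817. Heat shock and macrophage lists held with each array left out. Smooth muscle markers had adjusted p = 0.0519 and endothelial markers 0.355 without transgenic TAC 1, and immediate early genes 0.298 without wild-type TAC 2. SRF and MRTF targets had 0.19 without wild-type TAC 1, 0.187 without transgenic TAC 1 and 0.0557 without transgenic TAC 2.

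The comparison of genotypes after TAC used 4 of these 6 arrays, so the direction of each gene past the test over both surgeries was fixed beforehand. Nrxn3 rose by 3.97 ± 0.21 (15.7-fold, 2 against 2 arrays, adjusted p = 5.50e-04) and Sult4a1 by 3.00 ± 0.20 (adjusted p = 0.00172). Vgll2 (2.57), Alx4 (2.37), Rnf208 (2.36), Slc9a3 (2.25), Ckmt1 (2.15), Ttr (2.08), Cideb (1.53), the neuronal kinesin gene Kif5c (1.44), Ric3 (1.40) and Fxyd6 (1.34) rose as well. Acta2 fell by 1.94 ± 0.25 (adjusted p = 0.0296), and Pdlim3 (-1.67), Slc24a2 (-1.60), Hopx (-1.59), Abcb4 (-1.50), the enteric smooth muscle actin gene Actg2 (-1.43) and Aqp4 (-1.38) fell too. In all 23 genes passed, 16 higher and 7 lower, none of them with overlapping arrays, and 643 had an unadjusted p under 0.05 against 558 by chance; over all genes 32.3% did not overlap, where chance gives 33.3%. In limma the count was 0 with a floor of 64. Leaving out a TAC array, or both arrays of low Xist, leaves 1 array on a side. No count is given for those fits, and whether the calls hang on single arrays is not settled. Of SRF and MRTF targets 16 of 23 were lower (median -0.20, camera adjusted p = 5.28e-04), of which 5 passed adjusted over the list alone and 2 over all genes, and 12 of 14 heat shock genes were higher (0.15, adjusted p = 0.0132). With an estimated correlation both had adjusted p = 0.755, and both held with each array left out. Smooth muscle markers (0.340 without transgenic TAC 1), macrophage markers (0.280 without wild-type TAC 1), immediate early genes (0.773 without wild-type TAC 2, 0.127 without transgenic TAC 1) and endothelial markers (0.0994 without wild-type TAC 1, 0.189 without transgenic TAC 1) did not. Nor did oxidative phosphorylation (0.254 without wild-type TAC 2, 0.537 without transgenic TAC 2), unfolded protein response (0.0572, 0.0775 and 0.395 without wild-type TAC 1, wild-type TAC 2 and transgenic TAC 2) or fibroblast lists (0.798 without wild-type TAC 2, 0.970 without transgenic TAC 2).

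In the sham arrays, 1 of each genotype with no replicate check, Nrxn3 was 21-fold higher (log2 4.39) and Sult4a1 11.1-fold higher (3.48) in the transgenic array. Nmrk2 was higher by 2.97, Slc9a3 by 2.38, Rps4l by 2.34, Rnf208 by 2.31, Myh7 by 2.29 and the kallikrein gene Klk1b26 by 2.16. Lower genes were Xist (-5.09), Zbtb16 (-2.18), Hopx (-1.97), Cyp2e1 (-1.96), Ano10 (-1.76), Angptl4 (-1.73), Car3 (-1.60) and Ces1d (-1.50). A total of 74 genes were higher and 42 lower by log2 1 or more, where the SD over all genes was 0.33. The median of fetal and hypertrophic genes was 0.48, with 13 of 17 higher, that of heat shock genes 0.36, that of atrial markers 0.51 and that of macrophage markers 0.30, all at or above the 99.99th percentile of random lists. Adipocyte markers had a median of -0.60, below every random list, and endothelial markers -0.28, at the 0.06th percentile. The transgenic array of this pair is 1 of the 2 arrays of low Xist.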

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

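For the patterns weighed here, the tests of other splits of the arrays and of a chromosome segment were set out beforehand; those of animal sex, tissue RNA, the sham arrays and Xist hybridization were chosen only after the result was seen.

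In a test of the difference of the TAC responses, 7 gene lists had TAC differences that differed between genotypes by camera at the preset correlation, and none with an estimated correlation. Both arrays of low Xist enter this difference with a minus sign, so sex cannot be told apart from a differing response for these lists. The transgenic minus the wild-type difference was negative for fetal and hypertrophic genes (adjusted p = 5.48e-06), SRF and MRTF targets (5.73e-05), atrial markers (5.73e-05), heat shock genes (8.76e-05) and tricarboxylic acid cycle genes (2.36e-04). Of these, heat shock genes had a median TAC difference of 0.02 in wild type and -0.14 in transgenic arrays, and tricarboxylic acid cycle genes were lower after TAC in both, at -0.15 and -0.51. It was positive for adipocyte markers (0.00181), with medians of -0.38 in wild type and 0.28 in transgenic arrays, and for lymphocyte markers (0.00753). Leaving out transgenic TAC 2 gave 0.151 for tricarboxylic acid cycle and 0.0517 for lymphocyte lists, leaving out transgenic TAC 1 gave 0.0628 for adipocyte and for lymphocyte lists, and leaving out wild-type TAC 1 gave 0.0594 for lymphocyte markers.

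Among 3361 probes above the intensity filter that have no single gene symbol and entered no comparison of genes, 16 passed in limma between genotypes over both surgeries and 1 after TAC. The largest increases were at ILMN_1218717 (log2 3.24 ± 0.34) and ILMN_1260582 (2.32 ± 0.29), and the largest decreases at ILMN_2721198 (-1.33 ± 0.13) and ILMN_2444799 (-1.22 ± 0.15).

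The first pattern is the set of 106 genes past the test between genotypes over both surgeries. Animals of 2 sexes among the arrays are argued against as its whole origin, since each genotype had 1 array of low Xist and the Xist level correlated with genotype at 0.0285; with Xist as a covariate 53 of the 106 passed, as the median SE went from 0.14 to 0.15 with 1 residual degree of freedom fewer, while the median size of 1.01 was kept by this balance. A segment inherited with the transgene is argued against too: the fullest chromosome held 12.4% of the genes, and 28.9% of random draws put as many on 1 chromosome. RNA of other tissues cannot be told apart. Lists written without the genes that had passed had medians of -0.0161 (neuronal, 6 tested), -0.0433 (skeletal muscle, 7) and 0.0891 (hepatocyte, 4). With the genes that passed put back in, neuronal (median 0.683, SD 1.26), skeletal muscle (0.0794, SD 0.97) and hepatocyte lists (0.157, SD 1.21) held members that went both ways. Of these members 23 of 29, 9 of 16 and 9 of 13 had passed in this same comparison. The first lists are few in members and chosen to lack such genes, and the second restate them, so neither decides the question. The 6 arrays allow 10 splits into 3 and 3, too few for a share under 0.05; 1 split, the real one with 106 genes, gave as many and the highest other gave 0, and an effect of the transgene stays open.

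The second pattern is the smaller TAC difference of fetal and hypertrophic genes in transgenic arrays, with a list median of -0.43 and 12 of 17 members negative. A transgenic sham heart banded as strongly as the TAC hearts is argued against by Acta1, 1 gene of the list. Acta1 stood at 12.85 in transgenic sham beside 13.95 or more after TAC, and at 14.33 in wild-type TAC 2, the other array of low Xist. The list still had a median TAC difference of 0.522 in transgenic arrays. That median cannot be told apart from a possible difference in sex. A milder load on that heart cannot be told apart. Nppb (13.80) lay below all TAC arrays there, but Nmrk2 (11.87) lay above both wild-type TAC values, and Fhl1 (13.65) lay close to the wild-type TAC values of 13.71 and 13.97. Sex cannot be told apart from genotype here: with Xist as a covariate the median was -0.542, with 16 of 17 negative but an SD of 1.98 over the members. Chance level of a single sham array per genotype cannot be told apart either, as adjusted p = 0.795 with an estimated correlation and each genotype has 1 sham array. A transgene effect on sham hearts, where the list stood 0.48 higher, stays open and was not tested.

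The third pattern is low Xist on wild-type TAC 2 and transgenic sham. A failed hybridization is argued against, since all 4 Xist probes were low on both arrays. Animals of 2 sexes among the arrays are a candidate explanation: 2 of 4 genes that escape X inactivation, Kdm5c and Kdm6a, lay below the other 4 arrays on both, 0 lay above, and 2 of 8 Y-linked probes were higher on both. A Kdm5d probe, itself below the intensity filter, was at 6.24 and 6.44 beside at most 5.65. A Uty probe was barely higher, at 6.25 and 6.37 beside at most 6.23, and the other Y-linked probes did not separate the arrays. The labels give no sex, and no biological explanation from the design was tested.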

How the results depend on the processing

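The Xist covariate and the fits without the 2 arrays of low Xist were chosen after seeing the data. Where a setting changed a result, the cause was not tested. The fits without the arrays of low Xist have 1 residual degree of freedom and 1 wild-type TAC array, so they say little of stability. Quantile normalization again, median centring and a floor of 16 moved almost no value and say nothing of stability. A sham array was left out only where its comparison could still be fitted, and the lone array of a group was assumed to vary like the others.

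Counts of genes moved as follows. Between genotypes over both surgeries (106) there were 175 at an adjusted p under 0.1, 44 with a filter at the upper quartile, 59 with a floor of 64, 49 by the median over probes, 54 with Xist as a covariate and 24 to 474 without 1 array. After TAC between genotypes (23) there were 42, 38 with no filter, 11 with the upper quartile, 0 with a floor of 64, 10 over all probes, 5 by the median, 8 without a trend, 0 without the arrays of low Xist and 0 to 191 without 1 array. TAC against sham over both genotypes (1) gave 2 with no filter or the upper quartile, 0 without a trend or with the covariate, and 0 to 37 without 1 array. Within wild type (0) it was 5 with no filter, 10 with the covariate and 0 to 11, within transgenic arrays (0) 1 with no filter and 0 to 245, and for the difference of the responses (0) 5 with the covariate and 0 to 1. The sham pair (116) gave 712 at 1.5-fold, 196 over all probes and 3 in the 4-group limma fit. The correlation of the TAC responses was lowest, 0.0714, with wild-type TAC 2 and transgenic TAC 1 alone.

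Lists past camera were 0 in all 6 comparisons with an estimated correlation and with fry. Without the arrays of low Xist there were 9 of 14 for TAC over both genotypes and within wild type and 11 (from 6) between genotypes. The difference of the responses (7) had 4 with the upper quartile, 11 with the covariate and 9 to 13 without 1 array; the genotypes over both surgeries had 5 to 12 and wild type 9 to 15. Directions turned for fibroblast markers after TAC (adjusted p 0.438 with the covariate, 0.810 without the arrays of low Xist, 1.27e-05 to 0.970 without 1 array), and for immediate early genes in transgenic arrays (0.0785 with the covariate). Leaving out 1 array also turned cell cycle (3.27e-08 to 0.857) and endothelial lists (3.99e-08 to 0.748) in transgenic arrays, and endothelial (1.79e-08 to 0.189) and oxidative phosphorylation lists (4.51e-07 to 0.537) after TAC.

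As a replicate block, the TAC number gave 52 genes after TAC between genotypes and 4 within wild type. The numbers only name samples: the TAC 1 minus TAC 2 differences of the genotypes correlated at -0.0288.

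Signs of genes that had not passed also turned. By the median over probes these were Ankrd1 (0.064) and Atp2a2 (0.0039) after TAC; Atp2a2 for the difference (-0.0821), TAC (-0.0369), genotype (0.0312) and transgenic TAC (-0.0779); Kdm4a for the difference (-0.0546); Myh6 for the difference (-0.478), TAC (-0.223), after TAC (-0.389), transgenic TAC (-0.462) and wild-type TAC (0.0163); and Tbc1d10c for TAC (1e-04). With the covariate they were, for the difference, Acta1 (-0.0478), Atp2a2 (-0.104), Ccn2 (-1.16) and Nppb (-0.252); for transgenic TAC, Ankrd1 (-0.01), Kdm4a (0.108), Myh7 (-0.806) and Timp1 (-0.0283); and Ccn2 after TAC (-0.104). Without the arrays of low Xist they were Ankrd1 (-0.109), Ccn2 (-0.038), Myh6 (0.146) and Myh7 (-0.0208) for genotype, Ccn2 (-0.038), Myh7 (-0.0208) and Nppa (0.0032) after TAC and Myh6 (-0.0927) for TAC.

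Ranges without 1 array that crossed 0 were, after TAC, Ankrd1 -0.109 to 0.0584, Atp2a2 -0.170 to 0.0805, Ccn2 -0.038 to 0.927, Kdm4a -0.125 to 0.179, Myh6 -0.0165 to 0.232, Myh7 -0.0208 to 2.24, Nppa -0.101 to 0.0262 and Timp1 -1.02 to 0.132. For genotype they were Ankrd1 -0.0251 to 0.127, Ccn2 -0.001 to 0.550, Kdm4a -0.0865 to 0.0871, Myh6 -0.120 to 0.108, Nppa -0.0375 to 0.258 and Timp1 -0.445 to 0.240. For the difference they were Atp2a2 -0.0258 to 0.225, Ccn2 -0.0864 to 0.878, Kdm4a -0.0904 to 0.213 and Nppb -0.0713 to 0.118, for TAC Myh6 -0.0546 to 0.312, and for transgenic TAC Kdm4a -0.217 to 0.0866.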

Other observations

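Of the gene groups not described above, circadian clock genes were lower in transgenic arrays in 7 of 12 members over both surgeries (median -0.17), with Ciart at -1.01 ± 0.27 and Dbp, a clock output factor, at -0.66 ± 0.19 past the test over the list alone and 0 genes over all genes; camera gave adjusted p = 0.323. Antioxidant and metallothionein genes were higher in 10 of 12 (0.14, adjusted p = 0.199), with Srxn1 at 0.46 ± 0.15 and Mt1 at -0.26 ± 0.08. Unfolded protein response genes were higher in 12 of 17 (0.08, adjusted p = 0.0640), and of these the asparagine synthetase gene Asns rose by 0.93 ± 0.16 (adjusted p = 0.0376). Interferon response genes were higher in 13 of 15 (0.08, adjusted p = 0.0531). Histone demethylase and H3K9 methylation genes, the family of the transgene, had a median of 0.01 (9 of 15 higher, adjusted p = 0.683), with Kdm3a at 0.35 ± 0.14 and Kdm6b at -0.32 ± 0.14.

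After TAC over both genotypes, adult sarcomere genes had a median of 0.0075 (12 of 21 higher, adjusted p = 0.566), with a negative mean and a downward test, and included Cmya5 at -0.38 ± 0.09 and the muscle creatine kinase gene Ckm at -0.33 ± 0.11. Glycolysis genes were lower in 12 of 18 (-0.08, adjusted p = 0.148), with Pfkm at -0.25 ± 0.09 and Eno3 at -0.33 ± 0.12. Ribosomal protein genes had a median of 0.0034 (adjusted p = 0.650) with a negative mean, erythroid markers -0.04 (adjusted p = 0.470), antioxidant genes -0.09 (adjusted p = 0.959), clock genes -0.14 (adjusted p = 0.470) and histone demethylase genes -0.03 (adjusted p = 0.963) with a positive mean and an upward test. Between genotypes, adult sarcomere (adjusted p = 0.708), glycolysis (0.851), ribosomal protein (0.181) and erythroid lists (0.814) did not pass.

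Mthfd2 and Asns, both targets of the amino acid stress response, rose together in transgenic arrays. A hypothesis that they belong to a wider rise of that response was tested after this was seen, on a list of such genes without them. Its 12 tested members had a median of 0.0046 (SD 0.213, 6 higher) and ran from -0.17 (Vldlr) to 0.49 (Atf5). These values argue against a rise of the members as large as that of Asns. Camera was upward without passing (p unadjusted 0.166 in limma), so a smaller rise cannot be told apart from none.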
